A study of Danio rerio with 2 samples.

How the data were processed

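Zebrafish whole embryos and adult zebrafish were exposed for 48 h to 9 human hepatotoxicants, RNA was isolated from embryo samples and from dissected adult livers, and equal amounts of RNA were combined into 1 embryo pool and 1 liver pool, per the labels. The age of the embryos, the sex of the adults, the number of samples in each pool and whether unexposed samples were among them are not given in the sources used here. Each pool was sequenced as 1 library, and the file headers and values are those of a gene-level mapping table with 27098 features, the same in both libraries. The aligner, the gene annotation and the genome build are not given in the sources used here, so no coordinates are printed.

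The deposited files hold whole-number read counts for each gene region, per the file headers, as unique reads with 1 position and as total reads that also take in reads with several positions, and separately for exons, exon-exon junctions and intron-exon boundaries. The authors also deposited RPKM, in 2 identical columns, which equalled total exon reads divided by exon length and by the sum of total gene reads, on the usual scale of that unit, with a largest difference of 0.088 reads when recomputed. RPKM was 0 for the 1637 features to which the files give no exon length. The deposited median coverage, a signal value for each gene per the file headers, was not used here. Whether the counts are of reads or of fragments is not given in the sources used here. Unique reads made up 85.1% of the embryo counts and 80.2% of the liver counts, and exon reads 85.6% and 90.1%.

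Groups were taken from the tissue label, with 1 library in each. Total gene reads were the main counts, a choice made together with the size rule, the gene lists, the rule for named genes and most alternatives before the data were examined. That choice had been explained by total gene reads being the source of the authors' expression value, whereas RPKM turned out to come from total exon reads; total gene reads were kept, and total exon reads were added as an alternative after seeing the data. CPM values, counts scaled to a common library size, were computed from the total of each library, 11408727 counts for the embryo pool and 13020149 for the liver pool. The ratio of the pools was given with an exact 95% interval (Clopper-Pearson on the conditional binomial), and a gene was called higher in a pool where the interval lay wholly at or beyond 4-fold and that pool had at least 10 counts. Genes with at least 10 counts in either pool were taken as measured. A count of 0 was replaced by a floor of 3 counts per library for a bound on the fold and for list medians, which corresponds to 0.263 CPM in the embryo pool and 0.230 CPM in the liver pool. A fold given as at least a value is the ratio at this floor. The lower limit of its 95% interval lies below it, for rbp4l at 1158 against 1424. With 1 library per group no test between the sources was possible, and intervals compare these libraries only. Shares of genes carry exact binomial 95% intervals, which treat genes as independent and do not measure spread between libraries. Correlations used log2(CPM + 1).

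A set of 34 gene lists covered liver functions, xenobiotic metabolism, stress, the tissues of the embryo and other cell types that either sample could hold, and 33 had a measured member. The list of mitochondrially encoded genes matched no feature and was not analysed here. For each list the calls were counted, and the median log2 ratio was placed among 10000 random lists of the same size matched on mean log2 CPM in 20 bins, as a description of these libraries. Feature names were matched to current gene symbols through the RefSeq gene table of assembly GRCz12tu, used for names only: 18978 of 27098 features matched, 9009 by the same symbol, 5813 by a synonym and 4156 by gene number, and 407 features that lie at several positions were left out of the lists. List members were matched by the name in the files first and by the current symbol otherwise, a rule chosen after seeing the files. Named genes were the 10 most abundant of each pool, the 10 in each direction whose interval bound lay farthest from 1 among genes with at least 100 counts, up to 3 most abundant members of each list and the called member most against its median, and hnf4a, fabp10a, cyp3a65, cyp1a, abcb11b and the vitellogenins. Of the genes this rule names, 1 is not reported here. Further list members, such as those named where 5 or fewer members went 1 way, were chosen after their values were seen. Genes that share reads with paralogs, among them vitellogenins, globins, myosins and crystallins, are uncertain one by one.

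The calls were tested on simulated data, with Poisson counts drawn for the real genes at the real library sizes and some genes altered. Altered genes were drawn only from those with at least 50 expected embryo counts, so genes nearer the count minimum were not tested. Both simulated libraries had the same composition apart from these genes. The simulation therefore covered counting error only, not a shift in composition or differences between libraries. Of the genes altered by 8-fold and 16-fold toward the liver pool, 50 of 50 were called at each size, of those altered by 8-fold toward the embryo pool 46 of 50, and of those altered by 2-fold 0 of 50, as the 4-fold rule requires. Among 21003 unaltered genes 0 were called, and the intervals covered the true ratio for 95.7% of 21203 genes. Alternatives covered scaling, with TMM factors of edgeR 4.0.16 and size factors of DESeq2 1.42.0 in R 4.3.3, library totals without the 20 most abundant genes, the fold threshold, the count minimum, unique reads, RPKM with a log2 difference of at least 2, and thinning of the deeper library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for everything else.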

Results

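Gene expression was measured by RNA sequencing in 2 pooled zebrafish libraries, 1 of whole embryos and 1 of livers dissected from adult fish. Before RNA was isolated, embryos and adults had been exposed for 48 h to 9 compounds that are toxic to the human liver. These were acetaminophen, amiodarone, chlorpromazine, cyclosporine A, 17a-ethynylestradiol, paraquat, tetracycline, thioacetamide and valproic acid. An embryo sample held 15 embryos, and the RNA of the samples was combined in equal amounts into 1 pool for each source. Each pool mixed all exposures, so no value below belongs to a single compound, and no unexposed library was analysed here. Whether the pools also held RNA of unexposed fish is not given in the sources used here. The total count assigned to genes was 11408727 in the embryo pool and 13020149 in the liver pool, over 27098 gene features. With 1 library per source the differences had no replicate check, and no p-value was computed. The 95% intervals, given in brackets after ratios, and the floor of 3 counts used for genes with a count of 0 covered counting error only. A fold given as at least a value takes 3 counts in place of 0 and lies above the lower limit of its 95% interval. Where mates of a fragment or PCR copies were counted apart, which no table here measures, the intervals are too narrow.

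The most abundant transcripts of the liver pool were led by those of secreted plasma and yolk proteins, whereas the counts of the embryo pool were spread over many more genes. The 10 most abundant genes took 23.8% of the counts in the liver pool and 8.24% in the embryo pool, and the 100 most abundant took 53.1% and 23.6%. The first 50% of the counts were reached with 78 genes in the liver pool and 842 genes in the embryo pool. The most abundant liver transcript was vtg1, a vitellogenin or egg yolk precursor, at 87808 CPM in the liver pool and 28.6 CPM in the embryo pool. It was followed by the iron carrier transferrin tfa at 22510 CPM in the liver pool and 957 CPM in the embryo pool. Next came the apolipoprotein gene apobb.1 (apobl in the files) at 21898 CPM in the liver pool and 3653 CPM in the embryo pool, vtg2 at 19242 CPM in the liver pool and 7.19 CPM in the embryo pool, and apoa2 (zgc:193613 in the files) at 18823 CPM in the liver pool and 1224 CPM in the embryo pool. Complement component c3a.1 (si:dkey-76b14.4 in the files), the fetuin gene fetub, the elongation factor eef1a1l1 (ef1a in the files), the liver fatty acid-binding protein fabp10a (fabp10 in the files) and the mitochondrial carrier ucp1 (ucp4 in the files) completed the 10, with fetub 17.0-fold higher (16.7 to 17.4) and ucp1 22.5-fold higher (21.9 to 23.1) in the liver pool. In the embryo pool 7 of the 10 most abundant genes encode muscle proteins, led by the fast myosin heavy chain myhz1.1 at 19427 CPM in the embryo pool and 1.23 CPM in the liver pool. The alpha-actin actc1b had 10094 CPM in the embryo pool and 0.922 CPM in the liver pool. The remaining 3 were eef1a1l1 (ef1a in the files), the keratin krt4 and the unnamed feature LOC100151188, whose liver to embryo ratio of 0.938 became 2.395 under trimmed-mean (TMM) scaling. Reads shared between paralogs limited single values. Only 60.8% of the liver reads of vtg1, 15.8% of those of fetub and 31.9% of the embryo reads of myhz1.1 had 1 position.

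**Figure D1:**
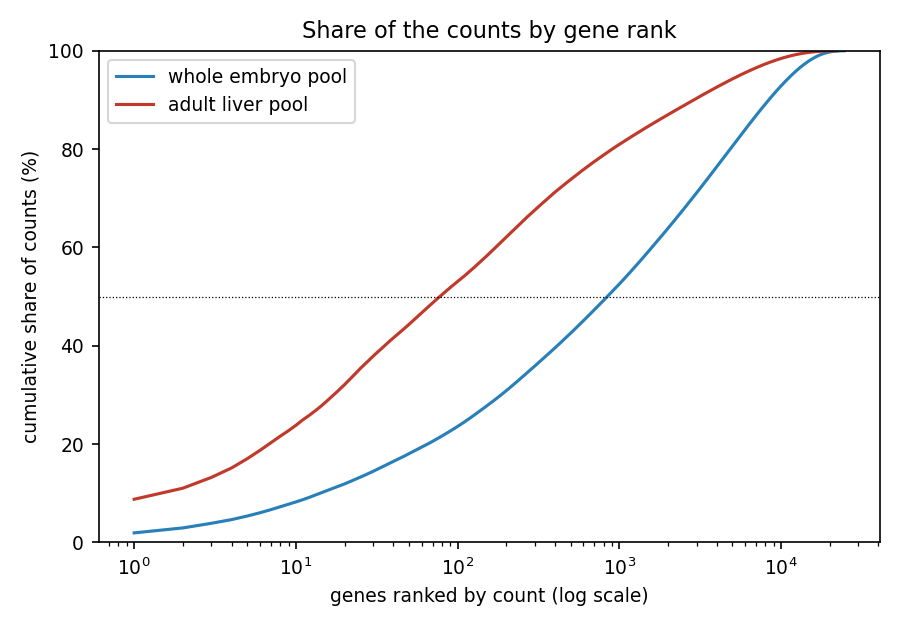
Cumulative share of the total gene count (%, vertical axis) against gene rank by count (horizontal axis, log scale) in the whole embryo pool and the adult liver pool. The liver curve reaches 53.1% at 100 genes and the embryo curve 23.6%, and the dotted line marks 50%.

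The title of the series asks whether the embryo can stand in for the adult liver in toxicity studies, and the first comparison was which genes of the liver pool were also found in the embryo pool. Of 16495 genes with at least 10 counts in the liver pool, 15846 (96.1%, exact 95% binomial interval over genes 95.8 to 96.4) also had at least 10 counts in the embryo pool. The embryo pool had 21101 detected genes among all 27098 features, and 15846 of them (75.1%, 74.5 to 75.7) were detected in the liver pool. Among the 728 genes called higher in the liver pool, 535 (73.5%, 70.1 to 76.7) were detected in the embryo pool and 71 had no embryo count. Genes of the liver function lists were present in the embryo pool, with 2773 embryo counts for fabp10a, 10915 for tfa, 481 for the ceruloplasmin gene cp and 170 for the nuclear receptor hnf4a. In a library of whole embryos these counts cannot be assigned to hepatocytes. Across the 21750 genes with at least 10 counts in either pool, log2(CPM + 1) values of the pools gave Spearman's rho of 0.551 and Pearson's r of 0.557. Both coefficients, and the intervals of the shares above, describe these libraries across genes, which are not independent replicates. The correlation rested on the count minimum, with rho at 0.417 for genes with at least 50 counts and 0.707 with no minimum.

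Far more genes were higher in the embryo pool than in the liver pool. With a gene called where the 95% interval of its CPM ratio lay wholly at or beyond 4-fold, 728 genes were higher in the liver pool, 6730 were higher in the embryo pool and 14292 of 21750 were called in neither direction. Of the genes higher in the embryo pool, 3059 (45.5%, 44.3 to 46.7) were still detected in the liver pool and 1482 had no liver count. The size of this asymmetry depended on scaling. The median log2 ratio of liver over embryo was -1.60 over all measured genes with library totals. TMM factors and median-of-ratios size factors shifted every ratio toward the liver pool by 1.35 and 1.38 on the log2 scale. With TMM factors 1754 genes were higher in the liver pool and 3427 in the embryo pool, and under size factors 1781 and 3362. The liver share of the calls went from 9.76% to 33.9% and 34.6%. No call turned to the other pool under either scaling, by construction, since each applied 1 shift to all genes that was too small to turn a 4-fold call.

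**Figure D2:**
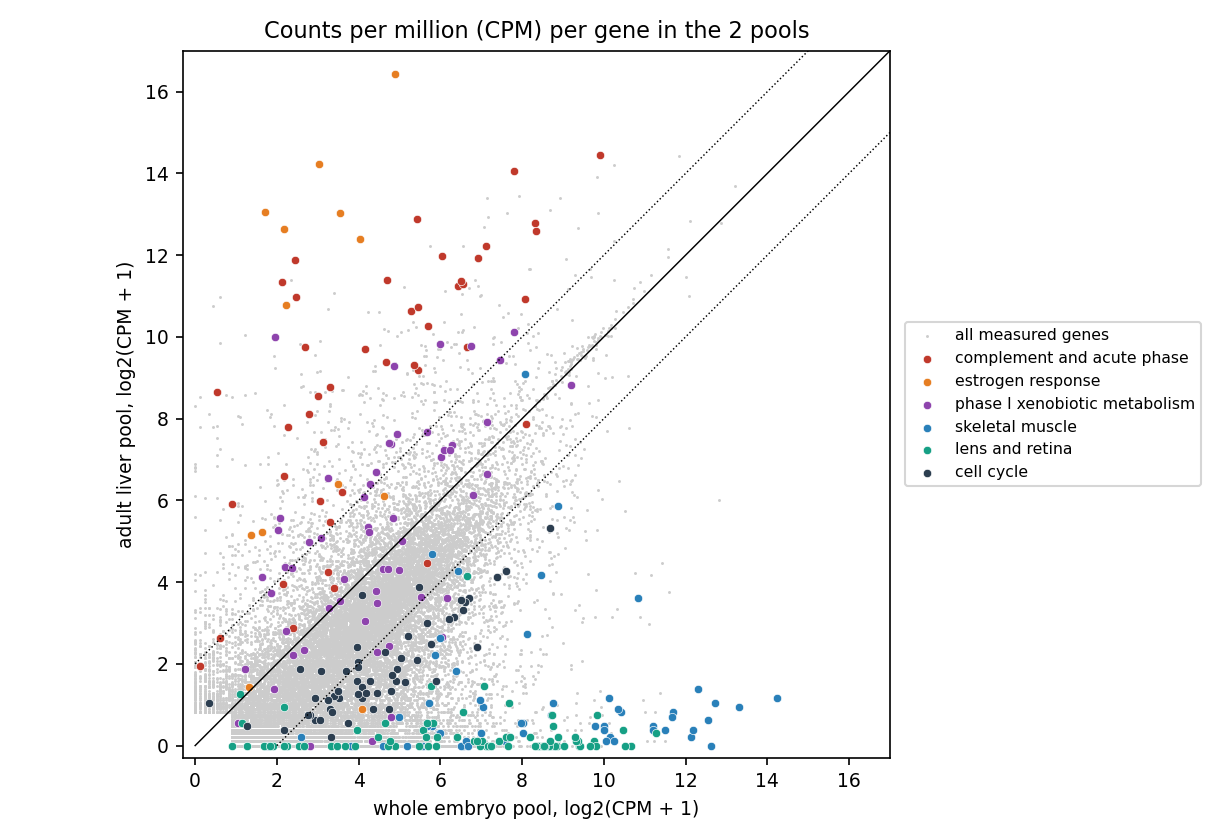
Each point is a gene with at least 10 counts in either pool, with log2(CPM + 1) in the whole embryo pool on the horizontal axis and in the adult liver pool on the vertical axis; the solid line marks equal values and the dotted lines 4-fold differences. Members of 6 gene lists are coloured, and those of the estrogen response and complement lists lie mostly above the upper dotted line while skeletal muscle and lens and retina genes lie mostly along the bottom. TMM scaling shifts every gene by 1.35 log2 units, which is too small to turn a 4-fold difference.

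Yolk precursors were the most abundant products of the liver pool and nearly absent from the embryo pool. The estrogen response list had 13 measured members, of which 10 were higher in the liver pool, 1 in the embryo pool and 2 in neither, with a median log2 ratio of 8.455. The vitellogenins summed to 1790113 liver counts, 13.7% of the library, against 815 embryo counts, a ratio of 1925 (1797 to 2064). Single family members ranged from vtg5, 3746-fold higher (2556 to 5735) in the liver pool, and vtg1, 3073-fold higher (2757 to 3436), down to vtg7 at 351-fold (303 to 409.5). Between them were vtg2 at 2677-fold (2157 to 3366), vtg6 at 1813-fold (1332 to 2539), vtg4 (zgc:136383 in the files) at 784-fold (657 to 944) and vtg3 at 479.7-fold (355 to 666). The exception was vtg8 (LOC560066 in the files), which had 2 embryo counts and 86 liver counts and a ratio of 37.7 (10.1 to 316). Unique reads were 66.2% of the family's liver reads, so the split between members is uncertain. The 3 estrogen receptor genes were also higher in the liver pool, with 24 embryo counts and 470 liver counts for esr1, 18 embryo counts and 452 liver counts for esr2a and 118 embryo counts and 1094 liver counts for esr2b. The brain aromatase gene cyp19a1b, an estrogen-responsive gene of glial cells, was 18.8-fold higher (10.25 to 38.3) in the embryo pool, a call kept with TMM factors and lost with size factors. Ethynylestradiol was among the exposures mixed in both pools, and the sex of the adults is not given in the sources used here. No unexposed library was analysed here, so the values of this list cannot separate the source from exposure or sex.

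Genes of plasma proteins were higher in the liver pool as groups. In the complement and acute phase list 37 of 44 measured members were higher in the liver pool, none was higher in the embryo pool, and the median log2 ratio was 4.80. Examples were c3a.1 (si:dkey-76b14.4 in the files), 77.1-fold higher (74.1 to 80.2), the copper-carrying ferroxidase gene cp, 178-fold higher (163 to 195), and tfa, 23.5-fold higher (23.1 to 24.0). In the coagulation list 19 of 26 measured members were higher in the liver pool and 1 in the embryo pool, with a median of 4.08. The fibrinogen gamma chain gene fgg was 49.8-fold higher (47.3 to 52.4), plasminogen plg 30.8-fold higher (29.2 to 32.6) and prothrombin f2 32.9-fold higher (30.7 to 35.4). The alpha and beta chain genes did not follow fgg. Called in neither direction with library totals or under TMM scaling were fga, with 768 embryo counts and 936 liver counts, and fgb, with 27 and 30. Why the chains differed was not tested. The fibrinogen-like gene fgl1 (LOC100003029 in the files), with 90 embryo counts and 2 liver counts, was 51.4-fold higher (13.8 to 431) in the embryo pool. Of 26 measured apolipoproteins and lipid carriers, 13 were higher in the liver pool and 5 in the embryo pool, with a median of 1.91. The liver-enriched group included fabp10a, 46.3-fold higher (44.6 to 48.0), apoa2, 15.4-fold higher (15.1 to 15.6), and apobb.1, 5.99-fold higher (5.93 to 6.06). The 5 genes higher in the embryo pool were apoda.1, apodb, fabp1b.1, fabp6 and the retinol carrier rbp4l. The last had 3744 embryo counts and 0 liver counts and was at least 1424-fold higher. Under TMM scaling 40 complement, 21 coagulation and 16 apolipoprotein genes were higher in the liver pool and 0, 1 and 5 in the embryo pool. The medians of the estrogen response list and of these 3 lists lay above those of all 10000 random lists of the same size matched on mean CPM.

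Hepatocyte transcription factors had a smaller median difference than the complement and coagulation genes. Of 21 measured hepatocyte regulators 5 were higher in the liver pool, 0 were higher in the embryo pool and the median log2 ratio was 1.53. Under TMM scaling 14 were higher in the liver pool. The 5 were hnf4b, 14.4-fold higher (11.7 to 18.1), hnf4a, 5.05-fold higher (4.29 to 5.98), the forkhead factor foxa2, the bile acid receptor nr1h4 and creb3l3a. The call of hnf4a was lost with exon reads. The homeobox gene prox1a (prox1 in the files) had a ratio of 2.46 (2.22 to 2.73) and cebpb of 1.97 (1.78 to 2.18), values called higher in the liver pool under TMM and size-factor scaling and not with library totals. In the bile acid list 9 of 27 measured members were higher in the liver pool and 4 in the embryo pool, against 14 and 1 under TMM scaling, with a median of 1.13. The fatty acid transporter and acyl-CoA synthetase slc27a2a (slc27a2 in the files) was 13.5-fold higher (12.6 to 14.5) in the liver pool, the organic anion transporter slco1d1 (zgc:163027 in the files) 11.1-fold higher (10.4 to 11.9) and the sterol carrier protein scp2a (scp2 in the files) 6.52-fold higher (6.21 to 6.85). The 4 members higher in the embryo pool were the bile acid transporter genes slc10a1, slc10a2 and abcb11a and the organic anion transporter gene slco1c1. Of these, slc10a2 was 39.9-fold higher (15.3 to 149) and alone kept the call under TMM scaling. The bile salt export pump gene abcb11b was not analysed here, since no feature matched it.

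Genes of intermediary metabolism were higher in the liver pool more often than in the embryo pool. Of 62 measured genes of gluconeogenesis, amino acid and one-carbon metabolism, 26 were higher in the liver pool and 6 in the embryo pool, or 37 and 4 under TMM scaling, with a median log2 ratio of 1.91. The tyrosine-degrading dioxygenase hpda (zgc:56326 in the files) was 51.2-fold higher (48.1 to 54.4) and adenosylhomocysteinase ahcy 7.11-fold higher (6.92 to 7.30). A second gene of that dioxygenase, hpd, went the other way, with 737 embryo counts and 0 liver counts, at least 280.4-fold higher in the embryo pool. Fatty acid and cholesterol genes were mostly within 4-fold, with 7 of 56 measured members higher in the liver pool, 3 in the embryo pool and a median of 0.71. Under TMM scaling these were 24 and 2. The desaturase fads2 was 40.9-fold higher (36.1 to 46.6) in the liver pool. The beta-oxidation genes acaa2 (zgc:56036 in the files) and acadm had ratios of 3.32 (3.15 to 3.50) and 1.91 (1.82 to 2.005) and were called under TMM and size-factor scaling and not with library totals. Another desaturase, scdb, was 152-fold higher (64.8 to 469.7) in the embryo pool, where acsl1a and acsl5 were also higher, acsl5 with library totals and not under TMM scaling. The medians of these 2 lists and of the hepatocyte regulator and bile acid lists lay above those of all 10000 random lists.

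Genes of xenobiotic metabolism, which process drugs and other foreign compounds, were detected in both pools. All 57 measured phase I genes had at least 10 counts in the embryo pool and 53 had them in the liver pool. Of these, 14 were higher in the liver pool, 6 in the embryo pool and 37 in neither, with a median log2 ratio of 0.99. Under TMM scaling 29 and 3 were called. The alcohol dehydrogenase adh8a was 350.1-fold higher (249 to 509) in the liver pool and the dioxin-inducible cytochrome P450 cyp1a 22.2-fold higher (19.8 to 24.9), with 71.4% of its liver reads unique. The carboxylesterases were also higher, ces3 at 14.5-fold (13.4 to 15.7) and ces2a (ces2 in the files) at 4.98-fold (4.78 to 5.20). The cytochrome P450 cyp3a65, which has its place in drug oxidation, had 453 CPM in the liver pool and 589.9 CPM in the embryo pool. Its liver to embryo ratio of 0.767 (0.741 to 0.795) was 1.96 under TMM scaling, a change of direction. cyp2aa8 (zgc:101673 in the files), another cytochrome P450, had 218 embryo counts and 1 liver count and was 249-fold higher (44.2 to 9871) in the embryo pool. Of 56 measured phase II and III genes, 7 were higher in the liver pool and 13 in the embryo pool, a balance that turned to 25 and 4 under TMM scaling, with a median of 0.88. The glutathione transferase gstt1a was 12.3-fold higher (11.4 to 13.3) in the liver pool, and gstp1.2 (gstp1 in the files) had a ratio of 1.94 (1.87 to 2.02), called under TMM and size-factor scaling and not with library totals. By contrast, gsto2 (zgc:101897 in the files) was 60.7-fold higher (40.3 to 96.2) in the embryo pool. Both medians lay above those of all 10000 random lists.

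Most stress genes were called in neither direction with library totals. Of 31 measured oxidative stress genes, 5 were higher in the liver pool and 0 in the embryo pool, with a median log2 ratio of 0.37 at percentile 99.9 of the random lists. Under TMM scaling 11 were higher in the liver pool. The 5 were the catalase gene cat, 16.4-fold higher (15.5 to 17.3), the glutathione peroxidases gpx4a, 11.01-fold higher (10.6 to 11.4), gpx1a, 9.33-fold higher (8.56 to 10.18), and gpx3, and the superoxide dismutase gene sod3a. None of 34 measured endoplasmic reticulum stress genes was called with library totals, and 13 were higher in the liver pool under TMM scaling, with a median of 0.34 at percentile 99.98. The chaperones p4hb, hsp90b1 and hspa5 had liver to embryo ratios of 3.83 (3.65 to 4.02), 2.85 (2.73 to 2.98) and 1.81 (1.73 to 1.89), each called under TMM and size-factor scaling and not with library totals. Without unexposed libraries these values hold no measure of induction.

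Contractile, sensory and neural genes separated the embryo pool from the liver pool almost completely. Of 62 measured skeletal muscle genes, 60 were higher in the embryo pool and 0 in the liver pool, with a median log2 ratio of -8.93. The list took 9.42% of the embryo counts against 0.0714% of the liver counts. The myosin gene myhz1.1 was 15809-fold higher (9735 to 27658) in the embryo pool, actc1b 10952-fold higher (6270 to 21196), and the calcium-binding parvalbumin gene pvalb2, with 71592 counts against 0, at least 27235-fold higher. The enolase gene eno3 and the regulator mef2d were the 2 members not called, and eno3, with 3052 embryo counts and 7118 liver counts, was higher in the liver pool under TMM scaling. In the heart muscle list 14 of 19 measured members were higher in the embryo pool, with a median of -4.71. They included the ventricular myosin myh7 (vmhc in the files), 220.3-fold higher (107 to 549), and actc1a, whose 2698 embryo counts and 1 liver count gave a ratio of 3079 (552 to 121662) with 23.7% of its embryo reads unique. Of 80 measured lens and retina genes, 76 were higher in the embryo pool, with a median of -9.28. The ultraviolet cone opsin opn1sw1 was 10836-fold higher (3708 to 52548), the lens crystallin crybb1l1 at least 6334-fold higher, and rhodopsin rho at least 7042-fold higher, although 3.08% of the rho reads were unique. The gamma-crystallins together had 94397 embryo counts, 51.8% of them unique, and 4 liver counts. Of 75 measured nervous system genes, 72 were higher in the embryo pool, with a median of -7.12. Among them were the creatine kinase ckbb, 148-fold higher (122 to 181), and the neuronal sodium pump atp1a3a, 746-fold higher (452 to 1334), and marcksl1b (zgc:85717 in the files), 20.3-fold higher (18.5 to 22.2). Under TMM scaling 54 muscle, 12 heart, 71 lens and retina and 68 nervous system genes stayed higher in the embryo pool, with 1 muscle and 1 heart gene higher in the liver pool.

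Connective tissue, skin, patterning and proliferation genes were also higher in the embryo pool. Of 44 measured cartilage, bone and connective tissue genes, 35 were higher in the embryo pool and 1 in the liver pool, with a median log2 ratio of -6.24. The cartilage collagen col2a1a had 27280 embryo counts and 1 liver count, a ratio of 31133 (5587 to 1229740), and the collagens col1a1a and col1a1b were 247-fold (212 to 289.9) and 97.7-fold (85.8 to 112) higher. The exception was the fibronectin gene fn1b, 32.3-fold higher (29.3 to 35.8) in the liver pool, with 22.2% of its liver reads unique. Of 40 measured epidermis genes, 33 were higher in the embryo pool, with a median of -5.90, led by the keratins krt4, 114-fold higher (106 to 122), and krt5, 1829-fold higher (1171 to 3039). Of 38 measured Hox genes, 34 were higher in the embryo pool with library totals and 24 under TMM scaling, with a median of -4.39. The gene hoxd3a, with 0 liver counts, was at least 116-fold higher, and hoxc3a was 114-fold higher (67.5 to 209) and hoxb3a 19.2-fold higher (14.8 to 25.3). Only 22.1% of the embryo reads of hoxc3a and 27.7% of those of hoxb3a lay in exons, and the exon-based RPKM of hoxc3a was 13.9 in the embryo pool and 0.237 in the liver pool, a smaller ratio. The cell cycle list lost the most calls under TMM scaling. With library totals 45 of its 56 measured members were higher in the embryo pool and under TMM scaling 9, against 32 connective tissue and 26 epidermis genes, while the median went from -3.29 to -1.94. The replication genes pcna and mcm7 and the histone chaperone gene anp32e were 10.1-fold (8.75 to 11.7), 10.7-fold (9.33 to 12.2) and 10.5-fold (9.54 to 11.5) higher in the embryo pool. None was called under TMM scaling, where the ratios were 3.95, 4.18 and 4.10. The medians of the skeletal muscle, lens and retina, nervous system, connective tissue, epidermis, Hox and cell cycle lists lay below those of all 10000 random lists, and that of the heart list at percentile 0.05.

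Blood genes showed an exchange of globins between the pools. All 5 measured adult globin genes had 0 embryo counts, with 3111 liver counts between them, and 4 were higher in the liver pool, or 5 under TMM scaling. The genes hbba1 (ba1 in the files), hbaa1 and ba1l were at least 449-fold higher, at least 258-fold higher and at least 181-fold higher, although only 51.4% of the family's liver reads were unique. Of 9 measured embryonic and larval globin genes, 8 were higher in the embryo pool, with 12262 embryo counts against 6 liver counts for the family and 37.1% of the embryo reads unique. Of the embryonic genes, hbbe1.1, hbae3 and hbbe2 were at least 1368-fold higher, at least 814-fold higher and at least 602-fold higher in the embryo pool. The median log2 ratio was 7.496 for the adult list, above all random lists, and -9.15 for the embryonic list, below all of them. Other erythroid genes had a median of -1.37 at percentile 61.3, with 5 of 15 measured members, rhag, cahz, slc4a1a, sptb and tal1, higher in the embryo pool. The ammonium transporter gene rhag was 75.6-fold higher (48.2 to 126) and the only 1 of the 5 still called under TMM scaling, where the list median was -0.02. The carbonic anhydrase gene cahz and the spectrin gene sptb, at 11.3-fold (8.89 to 14.6) and 12.3-fold (9.59 to 15.96), lost the call.

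Immune and stromal genes were mixed. Of 37 measured leukocyte genes, 4 were higher in the liver pool and 6 in the embryo pool, against 8 and 2 under TMM scaling. The median log2 ratio of -0.52, at percentile 99.99, became 0.83, and the summed CPM gave a liver to embryo ratio of 1.31 (1.26 to 1.37). The 4 higher in the liver pool were the antigen-presentation genes cd74a (iclp1 in the files), 54.0-fold higher (37.2 to 81.5), and cd74b, and the complement genes c1qb and c1qc. The neutrophil lysozyme gene lyz was 28.2-fold higher (16.2 to 53.5) in the embryo pool, spi1a (spi1l in the files), with 10.5% of its liver reads in exons, had a liver to embryo ratio of 1.85 (1.62 to 2.11), called under TMM and size-factor scaling and not with library totals, and rac2 of 0.328 (0.262 to 0.409). Of 33 measured genes of endothelium and stellate cells, 2 were higher in the liver pool and 9 in the embryo pool, against 4 and 4 under TMM scaling. The median of -1.08, at percentile 94.8, became 0.27. The metalloreductase steap4 (zgc:112143 in the files) was 20.9-fold higher (16.7 to 26.5) in the liver pool, where colec11 was also higher. In the embryo pool the smooth muscle actin acta2 was 13.5-fold higher (11.8 to 15.6), desma (desm in the files) 142-fold higher (81.1 to 276) and pdgfra 38.1-fold higher (23.2 to 67.1). Of these, desma is also in the skeletal muscle list, so its embryo counts cannot be assigned to stellate cells. In the bile duct list 5 of 16 measured members were higher in the embryo pool and 0 in the liver pool, against 4 and 3 under TMM scaling, with a median of -1.70 at percentile 9.75. Its summed CPM went the other way, with a liver to embryo ratio of 1.17 (1.15 to 1.19). The simple-epithelium keratins krt8 and krt18a.1 (krt18 in the files) had liver to embryo ratios of 1.22 (1.19 to 1.25) and 2.82 (2.71 to 2.93), the latter called under TMM and size-factor scaling and not with library totals. They had 1073 and 816 CPM of the list's 2337 CPM in the liver pool, and 878 and 290 CPM of its 2000 CPM in the embryo pool. The direction of the sum therefore rested on these keratins, which are also in the epidermis list. By contrast, cdh17 was 4.87-fold higher (4.43 to 5.36) in the embryo pool, a call lost under TMM scaling.

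Digestive enzymes of the pancreas were abundant in both pools. Of 31 measured exocrine pancreas genes, 30 were detected in the liver pool, 1 was higher there and 11 were higher in the embryo pool, or 6 and 7 under TMM scaling, with a median log2 ratio of -1.54 at percentile 2.65. The list summed to 9277 CPM in the embryo pool and 3304 CPM in the liver pool. The trypsins prss59.1 (zgc:66382 in the files) and prss1 (try in the files) had 17619 embryo counts and 6879 liver counts and 10563 embryo counts and 4525 liver counts. The elastase cela1.6 (zgc:92041 in the files), with under 40% of its reads unique in either pool, had a liver to embryo ratio of 0.484 (0.470 to 0.499) that was 1.24 under TMM scaling, a change of direction. The amylase amy2al1 (zgc:66313 in the files) was 228-fold higher (133 to 429) in the liver pool. Of 15 measured endocrine pancreas genes, 9 were higher in the embryo pool and 0 in the liver pool, with a median of -2.93 at percentile 14.9, or 7 and 1 under TMM scaling. The factor neurod1 (neurod in the files) was 390.0-fold higher (152 to 1433), isl1a (isl1 in the files) at least 282-fold higher and pcsk1 36.2-fold higher (22.1 to 63.8). Both neurod1 and isl1a are also in the nervous system list, so their embryo counts cannot be assigned to the pancreas. Of 37 measured intestine genes, 22 were higher in the embryo pool and 3, the chitinases chia.3, chia.5 and chia.6, in the liver pool, or 7 and 5 under TMM scaling, with a median of -2.66 below all random lists. The intestinal fatty acid-binding protein fabp2 was 10.4-fold higher (9.51 to 11.3) in the embryo pool, a call lost under TMM scaling, chia.2 (zgc:55941 in the files) 12.9-fold higher (11.8 to 13.98) there, and chia.6 (zgc:65788 in the files) 19.04-fold higher (16.1 to 22.7) in the liver pool. The apolipoprotein apoa4b.1 (apoa4 in the files) had a liver to embryo ratio of 1.51 (1.46 to 1.56). Of 27 measured kidney genes, 19 were higher in the embryo pool and 0 in the liver pool, or 10 and 0 under TMM scaling, with a median of -3.25 at percentile 0.135. These included the ion transporters atp1a1a.4, 36.1-fold higher (30.7 to 42.6), and slc4a4a, 27.8-fold higher (22.4 to 34.9).

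Ovary and oocyte genes were low in both pools, and their median and their sum pointed different ways. The sum was 225 CPM in the embryo pool and 169 CPM in the liver pool, a liver to embryo ratio of 0.750 (0.708 to 0.795) that lies on the liver side under TMM scaling. Of 34 measured members, 29 were detected in the liver pool and 17 in the embryo pool, and 7 were higher in the liver pool and 3 in the embryo pool, or 14 and 2 under TMM scaling. The median log2 ratio of 1.31 lay above those of all 10000 random lists. The egg envelope gene zp2.2, with 2 embryo counts and 135 liver counts and 8.15% of the liver reads unique, had a ratio of 59.15 (16.1 to 493) whose call was lost with unique reads. The luteinizing hormone receptor gene lhcgr, with 14 embryo counts and 315 liver counts and only 1.90% of the liver reads in exons, had a ratio of 19.7 (11.6 to 36.5) whose call was lost with exon reads. The 3 members higher in the embryo pool were ccnb1, ca15c and nanos1 (wu:fb76c12 in the files), the last 395-fold higher (70.4 to 15641). h1-10 (h1fx in the files), the most abundant member in the liver pool, had a liver to embryo ratio of 0.581 (0.538 to 0.628) that was 1.48 under TMM scaling, a change of direction. It supplied 144 CPM of the embryo sum and 83.9 CPM of the liver sum, so the direction of the list's sum rested on this gene.

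Ribosomal protein genes were nearly level between the pools on library totals. Of 78 measured genes, 1 was higher in the embryo pool and 0 in the liver pool, with a median log2 ratio of 0.11 at percentile 90.7 that became 1.46 under TMM scaling. The genes rplp0, rpl3 and rps2 (wu:fc94f01 in the files) had liver to embryo ratios of 1.38 (1.36 to 1.41), 1.098 (1.08 to 1.12) and 1.28 (1.26 to 1.302), with 2.01% of the liver reads of rps2 unique. The single call, rpl37, was 6.86-fold higher (5.51 to 8.62) in the embryo pool, but only 9.63% of its embryo reads lay in exons, and the call was lost under TMM scaling and its direction turned with exon reads. Genes often taken as references in expression studies were nearly level in sum on library totals but varied gene by gene. Their summed CPM gave a liver to embryo ratio of 1.003 (0.998 to 1.008). Of 23 measured, 6 were higher in the embryo pool and 1 in the liver pool, or 4 and 2 under TMM scaling. With library totals 16 were called in neither direction, against 14292 of all 21750 measured genes. The median of -0.48, at percentile 63.9, became 0.87 under TMM scaling. The beta-actin gene actb1 (bactin1 in the files) was 7.21-fold higher (6.93 to 7.501) in the embryo pool and not called under TMM scaling. The liver to embryo ratio of actb2 (bactin2 in the files) was 0.691 (0.681 to 0.700), and 1.76 under TMM scaling, a change of direction. That of eef1a1l1 (ef1a in the files) was 1.41 (1.4 to 1.42). The antigen-presentation gene b2m was 87.6-fold higher (67.5 to 116) in the liver pool.

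**Figure D3:**
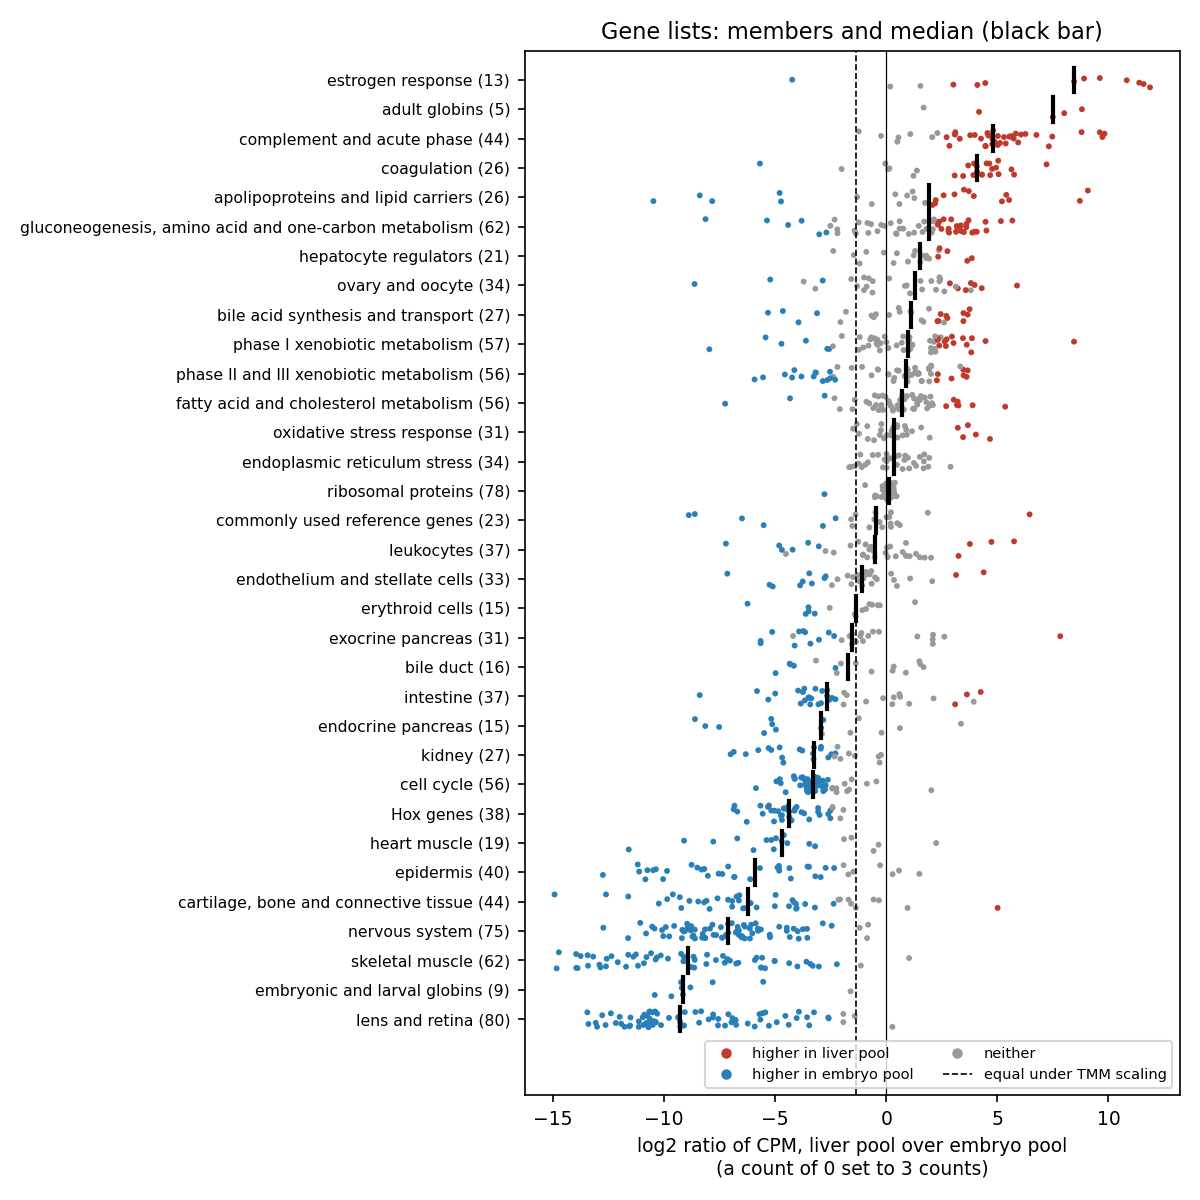
Log2 ratio of CPM, adult liver pool over whole embryo pool (horizontal axis), for the measured members of 33 gene lists (vertical axis, number of measured members in brackets), coloured by call, with black bars at the medians. Medians run from -9.28 for lens and retina to 8.455 for estrogen response, and the dashed line marks equality under TMM scaling, which puts the leukocyte, endothelium and reference gene medians on the liver side.

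The genes farthest apart between the pools added features outside these lists. Toward the liver pool, vtg1, vtg2, vtg4, vtg5 and vtg6 shared the first 10 places with cbln8 (zgc:171537 in the files), a cerebellin-like gene with 6 embryo counts and 26011 liver counts and a ratio of 3799 (1745 to 10352), and with the chemokine gene ccl39.2 (LOC100332947 in the files), which had 0 embryo counts against 4092 and was at least 1195-fold higher. The remaining features were si:ch211-133n4.9, 4202-fold higher (754 to 166021) from 1 embryo count, and the unnamed LOC100330726, 4894-fold higher (1911 to 17962), and LOC100330641, 1761-fold higher (809 to 4800). Of these, LOC100330726 had 1.93% of its liver reads unique. LOC100330641 had no annotated exon and by its deposited position lies between vtg4 and vtg6, so it may not be separate from that family. Toward the embryo pool, the muscle genes myhz1.1, actc1b, pvalb2, pvalb1, 29178-fold higher (8077 to 240936), tpma, 15167-fold higher (5924 to 55669), and mylpfa (mylz2 in the files), 11105-fold higher (5390 to 27623), were joined by the keratin krt1-19e (si:dkeyp-113d7.4 in the files), at least 6886-fold higher from 0 liver counts, and by col2a1a and rho. Another was ns:zf-e68, which had 32739 embryo counts and 1 liver count and 34.0% of its embryo reads unique. By its deposited position it lies between myhz2 and myhz1.2, so it may not be separate from the myosins. The remaining named genes followed their groups, with myhz1.2 6264-fold (3733 to 11458), myhz2 3127-fold (2046 to 5053), cyt1 1718-fold (1041 to 3070) and atp2a2a 9.19-fold (7.43 to 11.5) higher in the embryo pool, atp2a2a not called under TMM scaling.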

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

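The tests of multiply placed reads were chosen only after the result was seen. The read columns outside exons are given here because they entered no comparison on their own and were not empty, where a count of 0 would allow up to 3 reads (2.63e-05% of the embryo and 2.30e-05% of the liver reads). Reads outside annotated exons were 14.4% of the gene reads of the embryo pool (1637548 reads) and 9.87% of those of the liver pool (1284958 reads). Reads across an intron-exon boundary were 0.460% of the gene reads in the embryo pool and 0.466% in the liver pool.

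In 43 genes called higher in the embryo pool, with at least 1000 embryo reads each, under 10% of the reads lay in exons, 16 of them by construction because they have no annotated exon. Among the 27 with exons, led by frmd4bb (LOC100329900 in the files), with 31239 embryo and 274 liver reads, and LOC799819, with 28005 and 10, reads placed at several positions may account for much of the total, since 36.2% of their embryo reads were unique against 85.1% in the library. In the 16 features without exons 95.2% were unique, which argues against that source there, and with unique reads 93.0% of all 43 kept the call, so most calls did not need such reads, while 10 of the 27 with exons were called with exon reads. Unspliced transcripts of the same genes would cross exon boundaries, but the boundary index of the 27 genes, reads across boundaries relative to non-exonic reads and intron density, had a median 0.0180 times that of 9775 other genes. Unannotated transcripts inside these regions cannot be told apart from other sources, since 98.7% of the embryo reads of the 43 genes lay outside exons and the tables give no position for them, and a biological difference between embryo and liver was not tested here.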

How the results depend on the processing

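The alternatives with total exon reads, without genes of mostly shared reads and without genes that lack an annotated exon were chosen after seeing the data. Calls depended on scaling and on the fold threshold. Of 728 genes higher in the liver pool and 6730 in the embryo pool, the counts became 1754 and 3427 with TMM factors, 1781 and 3362 with size factors, 964 and 5485 with library totals without the 20 most abundant genes, 1404 and 11392 at 2-fold, and 419 and 4089 at 8-fold, the last 2 by construction. RPKM with a pseudocount of 0.1 gave 1116 and 9650, and 3 calls turned to the other pool; the cause was not tested. All 728 liver calls were kept with TMM and size factors by construction, since both shift every ratio toward the liver pool. Lists with most members higher in the liver pool went from 4 to 9 with either and to 7 at 2-fold.

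Of 112 named genes called, 102 kept the call with TMM factors, 101 with size factors, 111 with unique reads and 112 at equal library totals. Of the 111 with annotated exons, 108 kept it with exon reads and 109 with RPKM at a pseudocount of 0.1. Named genes were picked largely for abundance or distance between the pools, so these counts do not stand for all genes. Over all genes 3427 of the 6730 embryo calls were kept with TMM factors. The log2 ratio of rpl37 turned to 0.13 with RPKM and to 0.063 with exon reads, which leave out the reads outside exons that made up most of its embryo reads. Median log2 ratios changed sign with size factors for erythroid cells (0.01), and with TMM factors for leukocytes (0.83), endothelium and stellate cells (0.27) and reference genes (0.87).

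The share of liver-detected genes found in the embryo pool was 97.2% at 1 count, 96.8% at 3 and 93.7% at 50 counts (10621 liver genes), 94.8% at an RPKM of 1, 96.4% with unique and 95.3% with exon reads. Spearman's rho and Pearson's r were 0.417 and 0.420 at 50 counts and 0.707 and 0.672 with no minimum, and r was 0.505 with a pseudocount of 0.1. The 10 most abundant genes took 7.24% of the embryo and 24.1% of the liver counts with unique reads, 9.05% and 23.8% with RPKM, and 9.61% and 26.4% with exon reads. For these shares and correlations the cause was not tested. With 1 library per group none could be left out in turn, and depth limits the genes near 10 counts.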

Other observations

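The tests of tissue number and of pancreatic tissue were chosen only after the result was seen. Some related genes, also picked after their values were seen, differed in their counts in the pools. The retinol carrier rbp4 had 7132 embryo counts and 38222 liver counts, and rbp4l had 3744 embryo counts and 0 liver counts. The amylase amy2al1 had 13 embryo counts and 3383 liver counts and amy2al2 1760 embryo counts and 40 liver counts, while amy2a, with 3864 embryo counts and 2915 liver counts, was called in neither direction. The elongation factor gene eef1a1l1 was abundant in both pools, whereas eef1a1a had 1243 embryo counts and 3 liver counts. Among fatty acid-binding proteins, fabp10a had 2773 embryo counts and 146402 liver counts, fabp1b.1 4665 embryo counts and 200 liver counts and fabp6 882 embryo counts and 0 liver counts. The glutamine synthetase genes glula, with 5964 embryo counts and 1053 liver counts, and glulb, with 4261 embryo counts and 118 liver counts, were both higher in the embryo pool, glula not called under TMM scaling.

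Some liver genes are listed at an RPKM of 0 because the files give them no exon length. Of 667 measured features of this kind, 26 were higher in the liver pool and 182 in the embryo pool. The apolipoprotein gene apoc1 (apoc1l in the files) had 2235 embryo counts and 108069 liver counts, a ratio of 42.4 (95% interval 40.6 to 44.2), and apom had 551 and 8286, a ratio of 13.2 (12.1 to 14.4), both with an RPKM of 0 in each pool.

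The excess of embryo calls over liver calls, 9.24 to 1 with library totals, was 9.07 to 1 at equal library totals, and the liver library was the deeper, which argues against the difference in totals as its cause. Thinning did not equal out the depth left for typical genes, which belongs to the next explanation. A few liver genes taking most of the counts may account for part of it: the excess was at most 1.95 to 1 under TMM and size-factor scaling but 5.69 to 1 with library totals without the 20 most abundant genes. The first value lay between the bounds of 1, set beforehand for this as the whole cause, and 2, set for its exclusion, so the part of these genes cannot be told apart from that of other causes. The number of tissues in the whole embryo cannot be told apart either: at least 65.0% of the members of each of 5 tissue lists were higher in the embryo pool under TMM scaling, but the lists were written for tissues of the embryo and cover few of the calls.

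Exocrine pancreas genes took 3304 CPM of the liver pool, with 30 of 31 list members detected there and none of the list's members in another list. The tables argue against reads shared with paralogs, because the summed liver to embryo ratio with unique reads was 1.03 times that with total reads. Pancreatic tissue in the dissected livers cannot be told apart from expression by liver cells, which was not tested. For the 17 members with at least 1000 embryo counts the SD of the log2 ratio was 0.476 times that of all 1954 such genes, but genes of 1 cell type tend to a narrow SD, and the count minimum leaves out amy2al1, with 13 embryo counts and 3383 liver counts. Their log2 ratios still ran from -5.65 for c6ast4 to -0.32 for cel.2, the most abundant liver members being prss59.1 with 6879 counts and cela1.6 with 6598.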
